A study of Caenorhabditis elegans with 4 samples.

How the data were processed

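PQM-1 is a zinc finger transcription factor of the nematode Caenorhabditis elegans. The strain carried an extra copy of pqm-1, fused to GFP and epitope tags and integrated after bombardment, so that chromatin bound by the fusion protein was pulled down with an antibody against GFP. Per the labels' protocols, synchronized hermaphrodites were grown at 20 °C on bacteria to the third larval stage (L3), crosslinked with 2% formaldehyde, and sonicated, and the recovered DNA was size-selected and sequenced on an Illumina instrument. The wording of the chromatin protocol speaks of embryos, while the stage in the labels is L3. The labels list 4 libraries, an input and an anti-GFP ChIP library from each of 2 extractions.

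The values used here are 1 peak list for the whole series. Per the file headers, its coordinates are on WormBase WS180, and each row names PeakSeq as the source of the peak. PeakSeq compares the tags of a ChIP library in a candidate region with those of a control that it scales to the ChIP library. The only value the authors deposited for each peak is a q-value, written once as the score and once as an attribute. The list carries the word combined in its name and has no column for a single library. How the 2 replicates were combined, the aligner, the PeakSeq version and the read depth of each library are not given in the sources used here. The spread between replicates was therefore not analysed here, and no value below carries a replicate SD.

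The q-values were examined before any test. The q-value fell from one row to the next 2713 times. If both peaks have the same p-value and the q-value is the p-value divided by the rank, times a constant, the size of the fall gives the rank. In 2585 of the 2713 falls it gave the row number itself (relative tolerance 0.0001). The q-value was thus read as the p-value times the number of tested regions divided by the rank, with the row number as the rank. Every whole number from 5803 to 100000 was then tried as the number of tested regions, asking for how many of 200 randomly drawn peaks the p-value equals the lower tail of a binomial distribution with a chance of 0.5 (tolerance of 1e-11 on the natural log). The number 12873 matched 100% of the sampled peaks and the next best matched 0.5%. With 12873, exactly 1 pair of whole numbers gave the q-value of 5802 peaks, and 2 pairs did so for 1 peak, which was left out wherever tag numbers are used. Tag totals of up to 3000 per peak were searched first, and totals of up to 20000 only for peaks without a match there. A single pair is thus single within the range searched for that peak. These pairs are called ChIP tags and scaled control tags below, after the way PeakSeq tests a region. The scaled control tags are rounded and scaled by the caller, so they are not raw input reads. The recovery was tested on 5000 simulated peaks, of which 99.98% returned their true pair and 0 a wrong one. The simulated peaks had tag totals below those of the heaviest listed peaks and mostly higher ratios than the weakest, so these were hardly covered. They were drawn from the same formula, so the meaning of the recovered numbers was not tested.

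The ratio of ChIP to scaled control tags was computed per peak. Its 95% interval is the exact Clopper-Pearson interval of the ChIP share of the tags, turned into a ratio. It covers counting error only and takes the scaled control as a count. Medians over peaks carry bootstrap intervals from 2000 draws.

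Chromosome lengths were taken as the largest coordinate listed on each chromosome. Peaks were counted by midpoint in equal bins of about 1 Mb. The bins of X were compared with those of the autosomes by a 2-sided permutation test with 100000 resamples. Each autosome was divided into 3 equal parts, and each bin was assigned whole to the part that held its midpoint. The bins of the middle part were compared with those of the outer 2, with labels permuted within chromosomes. The recovery of tag numbers, the comparison of chromosome I with the other autosomes, the comparison of parts for each chromosome by itself and its difference between the autosomes and X were added after the data were seen. The 3 tests form 1 family for the Benjamini-Hochberg adjustment. Bins of a chromosome are not biological replicates, so these p-values describe this list and not a population of worms. Neighbouring bins resemble each other, while the permutation treats them as exchangeable, so the p-values may be too small even for this list. Rotation, which keeps neighbouring bins together, was run only for the comparison of parts, not for X or chromosome I. Simulated overdispersed bins were drawn independently of each other, so the resemblance of neighbouring bins was not simulated. Without any difference, 26 of 400 runs passed 0.05 for the X comparison and 13 of 400 for the comparison of parts. With a simulated fold of 1.5 these numbers were 396 and 399 of 400. The share of peaks with another midpoint within 1 kb was compared with 1000 lists redrawn uniformly within each chromosome, by a 1-sided test.

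The 10 peaks with the lowest q-value are named by position, a rule fixed before the data were examined for the case that no annotation could be used. All other peaks and windows named by position were chosen after their values were seen. The gene table at hand is on WBcel235, another build than WS180, and no coordinate of it is used in a result. The entry of pqm-1 in it, with its coordinates, was looked at beside the widest peak before the test of extra gene copies was chosen. Position relative to genes, sequence motifs, 6-mers, motif content by peak strength, bound genes, gene lists with cell type markers, and RNA biotypes had been planned, and are not analysed here. Alternatives fixed before the data were examined were the 2901 and the 1000 best peaks by q-value, bins of 2 Mb and 500 kb, merging of close peaks and a neighbour distance of 2 kb. Those added later were the removal of chromosome I, of peaks under 100 bp and of peaks with a ratio under 2, a control raised to a common level, rotation of the bins, and redrawing within 1 Mb. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.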

Results

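The in vivo binding regions of PQM-1::GFP were mapped in L3 hermaphrodites by ChIP-seq against the GFP tag, with input DNA as the control. The labels give 2 anti-GFP ChIP and 2 input libraries, which the authors reduced to 1 combined list. The comparisons this allows are ChIP against input at each region, and regions against each other along the genome. No value per replicate was analysed, so the differences below are set against counting error or against the spread between parts of the genome.

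The combined list held 5803 separate regions called for PQM-1::GFP on the 5 autosomes and X. Together they covered 2.71 Mb, or 2.71% of the 100.2 Mb spanned by the listed coordinates (WormBase WS180). The regions had a median width of 382 bp, with 302 and 520.5 bp as the 25th and 75th percentiles. The q-value of the regions ran from 3.85e-145 to 0.0098, with a median of 2.29e-06. In all, 1698 regions had a q-value under 1e-10 and 604 had one under 1e-20. No regions overlapped, and the smallest gap between neighbours was 200 bp.

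The q-values resolve into whole numbers of tags, which give the depth behind each region. The listed regions were 45.1% of 12873 tested ones. The median region held 83 ChIP tags against 27 scaled control tags, and from the 5th to the 95th percentile the regions held 35 to 237 ChIP tags. The median ratio of ChIP to scaled control tags was 2.91, with 2.33 and 3.84 as the 25th and 75th percentiles. A ratio of at least 5 was reached by 653 regions (11.3%), and one of at least 10 by 27 regions. A ratio under 2 was found in 520 regions (8.96%). The regions with the highest ratios were thus few, and most of the list consisted of regions with a moderate excess of ChIP tags.

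**Figure D1:**
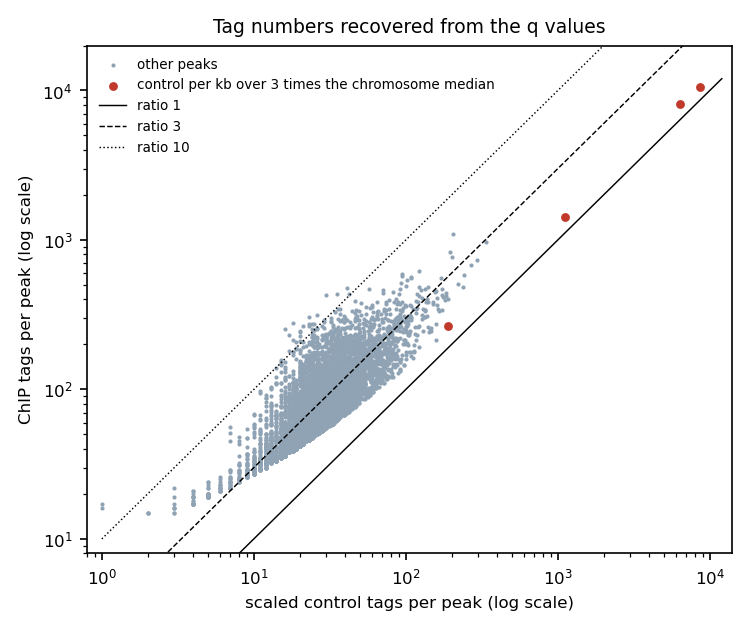
Each point is 1 of the 5802 peaks with a single solution, with its scaled control tags on the x axis and its ChIP tags on the y axis, both on log scales, and lines at ratios of 1, 3 and 10. The 4 red points are the peaks of 300 bp or more whose control per kb exceeded 3 times the median of their chromosome, and all 4 lie close to a ratio of 1.

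The 10 strongest regions by q-value were spread over the 5 autosomes, with 4 on chromosome IV, 3 on V, 1 each on I, II and III, and 0 on X. They held between 426 and 1103 ChIP tags. The strongest lay at V 723663 to 728373. It was 4711 bp wide and held 1103 ChIP tags against 205 scaled control tags, a ratio of 5.38 (95% interval 4.63 to 6.28). The second, at II 2378327 to 2379123, was 797 bp wide, held 478 against 41 tags and had a ratio of 11.7 (95% interval 8.47 to 16.5). The third lay at V 9076487 to 9080499, spanned 4013 bp and had a ratio of 4.27 (95% interval 3.65 to 5.02). Regions of higher ratio followed at IV 13919121 to 13919602, with a ratio of 14.2 (95% interval 9.80 to 21.3), and at IV 14594128 to 14594773, with a ratio of 12.5 (95% interval 8.82 to 18.1). The remaining 5 lay at I 1815349 to 1817049, III 599092 to 601196, IV 3227485 to 3228209, V 13462596 to 13463367 and IV 11913120 to 11916408. Their ratios were 6.21, 6.01, 10.3, 8.28 and 5.01 in that order. The 10 regions therefore held both broad domains of over 1000 bp (5 of 10), with ratios of 4.27 to 6.21, and regions of 482 to 797 bp with ratios of 8.28 to 14.2, and the intervals of the third region and of the region at IV 13919121 did not overlap. The genes at these positions were not analysed here.

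Strength went with width. With the list split by q-value into 4 groups of equal size, from the strongest to the weakest, the median width fell from 527 to 405, 338 and 281 bp, and the median number of ChIP tags from 165 to 94, 65 and 48. The median ratio went from 4.68 to 3.22, 2.57 and 2.21 over the same groups, and the median control from 34 to 29, 25 and 22 tags. Across 5802 peaks, Spearman's rho was 0.64 between width and -log10 q, and 0.13 between width and ratio. Peaks are not independent replicates, and the q-value depends on the number of tags, so these are descriptions of the list. Among the narrowest regions, 64 were under 100 bp wide. The 63 of these with a single solution had a median of 19 ChIP against 5 scaled control tags, and none was among the first 1000 rows of the list. A single base at I 4317367 was listed with 17 against 4 tags, a ratio of 4.25 with a 95% interval of 1.39 to 17.4.

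How the regions were shared among the chromosomes was compared next. The X chromosome, which hermaphrodites carry in as many copies as each autosome, had the highest density, with 1258 regions, or 71.0 per Mb. Chromosome I had the lowest, with 543 regions, or 36.0 per Mb. The other 4 autosomes lay close together, at 56.0 per Mb on II (856 regions), 61.4 on III (845), 59.99 on IV (1048) and 59.93 on V (1253). Over 1 Mb bins, X held 71.0 ± 19.6 peaks per Mb (SD, n = 18 bins) and the autosomes 55.1 ± 21.3 (SD, n = 82 bins), a ratio of 1.29 (2-sided permutation test, p = 0.00471, adjusted over 3 tests 0.00471). Chromosome I held 36.0 ± 15.1 peaks per Mb (SD, n = 15 bins) against 59.4 ± 20.2 (SD, n = 67 bins) on the other autosomes, a ratio of 0.61 (2-sided permutation test, p = 0.0001, adjusted 0.00015). The test of chromosome I, the lowest autosome, was added after the data were seen, and its p-values do not allow for that choice. Without chromosome I, the ratio of X to the autosomes was 1.196 (permutation p = 0.0317). Regions with a q-value under 1e-10 followed the same order at the ends, with 21.4 per Mb on X and 8.76 per Mb on I.

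The scaled control of the listed peaks differed between chromosomes. How the caller scaled the control was not recovered, so a scaling that differs between chromosomes cannot be told apart from a difference in input reads. In peaks of 300 to 500 bp, the median scaled control was 85.7 tags per kb on chromosome I (95% interval 82.2 to 88.8, 297 peaks). It was 72.8 on II, 70.7 on III, 70.6 on X, 64.5 on V and 61.9 on IV (95% interval 59.7 to 65.4, 472 peaks). The intervals of chromosome I and of each other chromosome did not overlap. The median ChIP density of the same peaks lay between 220.8 and 229.1 tags per kb on all 6 chromosomes, with overlapping intervals. The median ratio over all peaks was correspondingly lowest on I, at 2.45 (95% interval 2.37 to 2.51), and highest on IV, at 3.17 (95% interval 3.10 to 3.24).

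**Figure D2:**
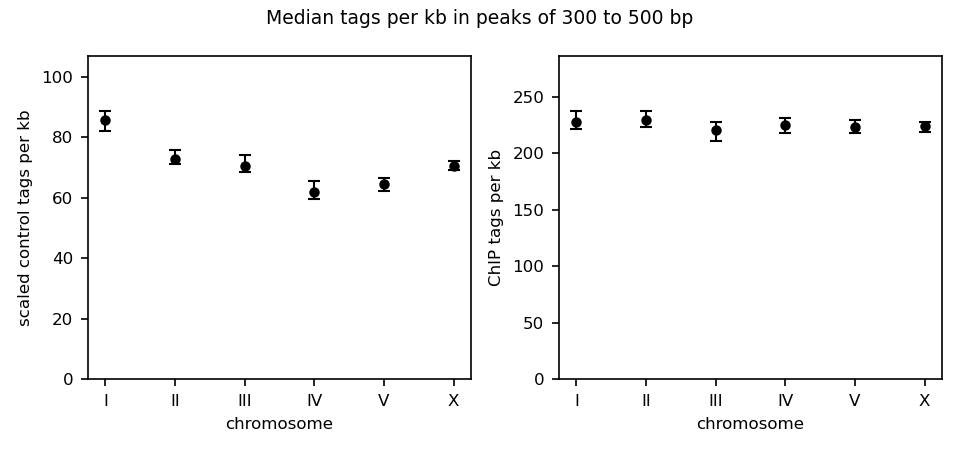
Median scaled control tags per kb (left) and ChIP tags per kb (right) in peaks of 300 to 500 bp on each chromosome, with 95% bootstrap intervals over peaks as bars and both y axes starting at 0. The control is highest on chromosome I, at 85.7 tags per kb, while the ChIP medians lie between 220.8 and 229.1 tags per kb.

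Within the autosomes, PQM-1::GFP regions were concentrated in the centres. In this species the autosome arms recombine more and hold fewer conserved genes than the centres. Each autosome was divided into 3 parts of equal length, and whole bins were assigned by midpoint, so the compared lengths were only about equal parts. On III, 4 bins were middle and 10 outer, and its densest bin, at 82.3 peaks per Mb, counted as outer. The middle parts held 74.3 ± 17.9 peaks per Mb (SD, n = 26 bins) and the outer parts 46.2 ± 16.4 (SD, n = 56 bins), a ratio of 1.61 (2-sided permutation test within chromosomes, p = 1e-05, the smallest that 100000 permutations can give, adjusted 3e-05). Each autosome showed it, with ratios of 1.72 on I, 1.82 on II, 1.28 on III, 1.70 on IV and 1.64 on V, and permutation p-values adjusted over 6 chromosomes of 0.0102, 0.00108, 0.0418, 0.00108 and 0.00328. On X the middle part held 80.3 ± 21.2 peaks per Mb (SD, n = 6 bins) and the outer parts 66.4 ± 17.9 (SD, n = 12 bins), a ratio of 1.21 that did not pass (permutation test, p = 0.165, adjusted 0.165). The log2 ratio of middle to outer was 0.68 on the autosomes together and 0.27 on X. Their difference was 0.41, with a bootstrap interval over bins of 0.0087 to 0.81, which only just excluded 0. Gene density was not used to adjust these values. The control and the mappability of reads were not compared between the middle and outer parts.

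**Figure D3:**
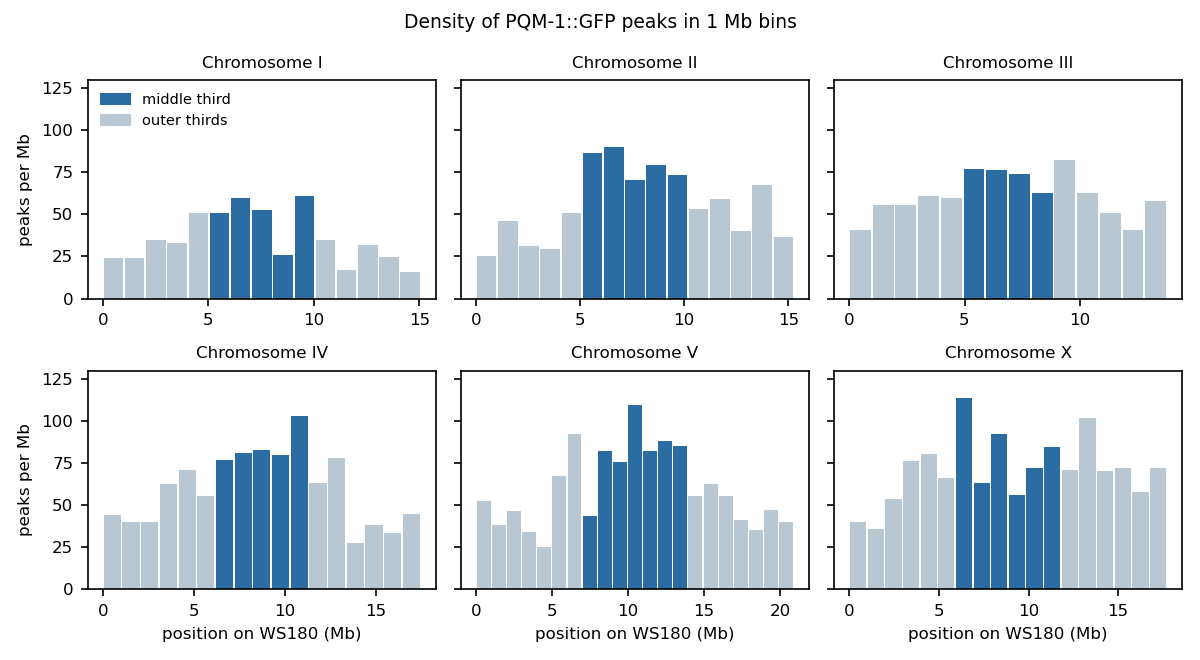
Peaks per Mb in equal bins of about 1 Mb along each chromosome (x axis, position on WS180 in Mb), with bins of the middle part in dark blue and of the outer parts in grey. Middle bins stand above outer bins on the autosomes, at 74.3 against 46.2 peaks per Mb on average, and chromosome I is low along most of its length.

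The regions also lay closer together than uniformly scattered positions would. Of the 5803 peaks, 925 (15.9%) had another peak midpoint within 1 kb, against 11.2% ± 0.552 (SD over 1000 uniform redraws), a ratio of 1.42. No redraw exceeded 12.9% (1-sided permutation test by redrawing positions, p = 0.000999, the smallest that 1000 redraws can give). The median gap between neighbouring regions was 6.39 kb and the longest was 283.5 kb. Among 1005 windows of 100 kb, the median held 5 peaks and 49 windows (4.88%) held none. The densest window, IV 4400001 to 4500000, held 23 peaks, above the highest count of 22 found in any window of the uniform redraws. It was followed by V 6200001 to 6300000 with 22 peaks and X 13300001 to 13400000 with 20. When peaks were redrawn only within their own 1 Mb bin, the ratio for neighbours within 1 kb was 1.31. The redraws ignore gene density and let midpoints fall at any distance, while listed peaks had a smallest gap of 200 bp. The size of these ratios therefore depends on the uniform redraws.

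A few regions stood out by their control. The widest region of the list, II 11138441 to 11161066, spanned 22626 bp, against 4711 bp for the next widest. It held 10560 ChIP and 8683 scaled control tags, a ratio of 1.22 (95% interval 1.182 to 1.251), and had a q-value of 5.21e-40. Its neighbour at II 11132482 to 11136318 held 1418 against 1116 tags, a ratio of 1.27 (95% interval 1.17 to 1.38). The last region of chromosome I, at 15064004 to 15067640, held 8160 against 6329 tags within 3637 bp, a ratio of 1.29 (95% interval 1.248 to 1.333). The fourth, at III 10224449 to 10225338, held 264 against 189 tags, a ratio of 1.40 (95% interval 1.15 to 1.69). These 4 were the only regions of 300 bp or more whose control per kb exceeded 3 times the median of their chromosome. All 4 ratios lay below the 5th percentile of the list, 1.87. These 4 regions, the single base on chromosome I and the windows above were chosen after their values were seen.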

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

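All 26 alternatives with a test kept the direction of their result and its side of the 0.05 threshold. Merging peaks that overlap or have midpoints within 200 bp could change nothing, as the smallest gap was 200 bp. The ratio of X to autosomes lay between 1.196 and 1.35 over 8 alternatives, with permutation p-values from 0.00036 to 0.0431, the highest for the best 1000 peaks. The ratio of chromosome I to the other autosomes lay between 0.42 for the best 1000 peaks and 0.80 for a control raised to a common level (7 alternatives, permutation p from 1e-05 to 0.0397). The ratio of middle to outer parts lay between 1.60 and 1.97 over 8 alternatives, with permutation p-values from 1e-05 to 0.0001, the highest from rotating the bins within chromosomes and the smallest that 10000 rotations can give. The excess of neighbours lay between 1.31 and 1.98 over 3 alternatives. The comparison of chromosome I and the settings that dropped chromosome I, narrow peaks or low ratios, raised the control, rotated bins or redrew within 1 Mb were chosen after seeing the data. Peaks per gene in each bin, and the alternatives of all results that need a genome or an annotation of the same build, were not run. No paired analysis was possible because the values are 1 list combined over both replicates, and leaving out a replicate was not possible for the same reason. The effect of depth was not tested; tag numbers were low in the 63 peaks under 100 bp, with a median of 19 ChIP against 5 scaled control tags.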

Other observations

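In the patterns below, the tests of extra gene copies, of dense binding and of repeat reads were chosen after their values had been seen, and the other tests before. For the tests of the control on chromosomes I and X, bootstrap intervals were added once the permutation p-values were known.

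The peaks in this paragraph were chosen after their values were seen. The highest ratio of the list, 17, belonged to a peak under 100 bp. Among peaks of 100 bp or more, the highest ratio, 15.9 (95% interval 9.59 to 28.2), was at II 1851731 to 1852111, with 254 ChIP against 16 scaled control tags in 381 bp. The next was 15.5 (95% interval 9.63 to 26.5), at V 8768400 to 8768873, with 279 against 18 tags in 474 bp. Others of this kind lay at IV 17245137 to 17245580 with a ratio of 13.7, at V 6614318 to 6614879 with 13.2 and at III 154138 to 154580 with 12.6. Their intervals overlap widely, so their order is not resolved. Across peaks, the ratio and the control per kb had a Spearman's rho of -0.61, as the ratio has the control as its divisor.

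The widest peak, at II 11138441 to 11161066, held many control tags, and whether these come from extra copies of the tagged locus or from another repeat cannot be told apart. Its control held 384 tags per kb, 6.37 times the median of the 266 other peaks of 1 kb or more (60.3). This lay above their 99th percentile (143), as extra copies or another repeat would give. The last peak of chromosome I held more, at 1740 tags per kb, which does not bear on the copies of this region. The limit first written for extra copies, this percentile together with the chromosome of pqm-1 (II in the WBcel235 gene table), was met. Comparison with the highest other peak was added once the value was known, and the question was first left open on it. That comparison cannot decide between extra copies and another repeat, as both would raise the control. The entry of pqm-1, with its coordinates on that other build, had been seen before the test was chosen, so it prompted the explanation and is not counted for it, and its position on WS180 was not analysed here. Joining of ordinary neighbouring peaks is argued against by the longest chain that other peaks form when gaps of up to 1000 bp are joined, 10211 bp, and dense binding alone by a ratio of 1.22, below the 5th percentile of the same 266 peaks (1.69, median 3.07), while some binding within the region stays open.

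A heavier scaled control was considered as an explanation of the low density on chromosome I. The control of every other chromosome was raised to the median of chromosome I, and the same p-value limit was kept. Then 542 peaks with a single solution stayed on I and 69.6% to 83.4% of the peaks on the others. The ratio of I to the other autosomes went from 0.61 to 0.80 (bootstrap interval 0.63 to 0.99, permutation p = 0.0397). This ratio could only rise, as peaks could be lost elsewhere but not on I, and peaks missed on I could not be restored. The rise itself is therefore not counted for the control. The bound set beforehand against this explanation, a ratio below that of the lowest other autosome with p under 0.05, was met, as IV stood at 0.90; but 0.90 lies inside the interval, so the bound was not met by more than the spread, and the control as the whole cause cannot be told apart from a difference in binding. That reads of repeats raised the control of their whole chromosome was taken to ask for the highest control on I and II. It was 85.7 tags per kb on I and 72.8 on II (95% interval 71.0 to 75.9), but the interval of II overlaps that of III (68.4 to 74.3). III also held 1 of the 4 regions of heavy control, so this overlap decides nothing, and raw input reads were not analysed here. As background, the tandem ribosomal RNA genes lie at the right end of chromosome I, where the last listed peak held 1740 control tags per kb.

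The higher density on X was not removed by the control. In peaks of 300 to 500 bp, the scaled control on X, 70.6 tags per kb, lay within the range of the autosomes (61.9 on IV to 85.7 on I). A lighter scaled control on X was thus not seen in these peaks, and the test below had little room to lower the ratio. With the control raised to a common level, the ratio of X to autosomes was 1.33 (bootstrap interval 1.15 to 1.55, permutation p = 0.00075), against 1.29 as listed. A lighter control on X as the whole cause asked for 1.1 or less, which lies below that interval, although the interval reaches below 1.2, the bound set beforehand against it. The excess on X lay mainly in its outer parts, which held 66.4 peaks per Mb, against 29.1 (I) to 56.8 (III) on single autosomes. The middle part of X, at 80.3, was near those of II (80.1), IV (84.7) and V (80.9) and above those of III (72.7) and I (49.97). This split was seen in the data and was not tested. The number of genes per Mb and the gene content of X, which differ from those of autosomes, were not tested and remain open explanations, as does the mappability of reads.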
